A study of Mus musculus with 12 samples.

How the data were processed

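Poly(A) RNA from dorsal root ganglia of adult mice was sequenced in 12 libraries, 6 from inducible Prdm12 knockout (iKO) animals and 6 from controls, per the labels. Tissue was kept frozen in TRIzol and libraries were made with a TruSeq kit that does not record the strand of the transcript, per the labels' protocols. Reads were handled with bcl2fastq 2.20.0.422, STAR 2.7.8a and featureCounts 2.0.1 on the GRCm39 mouse genome, per the submitters' processing notes. The annotation release and the counting options, such as the treatment of reads that map to several genes or that overlap several genes, are not given in the sources used here.

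The deposited values are raw counts per gene, with 1 table for each library and 55416 genes in each, and the authors applied no normalization to them. Whole numbers in every table and totals that differ between libraries fit this unit. Total counts ran from 13943784 to 20377766 per library. Counting error was therefore small for most genes tested, and the spread between libraries, a biological coefficient of variation of 12.8%, set the precision. Gene symbols came from an annotation of an older mouse genome build by matching gene identifiers, which named 52083 of the 55416 identifiers (94%), and these held 99.67% of all counts. Because the builds differ, that annotation was used only for names, gene classes, neighbouring genes and overlaps between genes, and no positions are given.

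Groups, replicate numbers, sex, injected agent and genotype were taken from the labels. Nothing in them says whether a library holds ganglia of 1 animal or of several, so p-values measure the spread between these samples. Counts were scaled by the trimmed mean of M-values (TMM) and filtered with edgeR's filterByExpr by group, which kept 16384 genes. Each was tested with edgeR's quasi-likelihood test in edgeR 4.0.16 (R 4.3.3), with robust estimates, sex as a term beside group and 9 residual degrees of freedom. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Expression values (CPM) are counts over the TMM-scaled library size and given as mean ± SD. The difference between the sexes, its interaction with group, and the iKO group against the tamoxifen-injected and the corn-oil controls separately were tested over all 12 libraries. Corn oil against tamoxifen was tested within the 6 controls, where 16791 genes passed the filter.

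In all, 38 lists of genes with a shared function, cell type or process were fixed before the data were examined, as were the tests, the alternatives other than those named below, and the rule for the genes named in the text. Of their 661 entries 656 matched a gene. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, on log2 CPM with a prior count of 2. Camera compares a list with all other genes. The fry test asks whether the genes of a list move on balance in 1 direction, and its mixed version whether they change in either. Counts of members past the threshold are given both over all genes tested and adjusted over the list alone. A marker score per library is the mean over a list of log2 CPM centred on each gene's mean, compared between groups by an exact permutation test over the 924 relabellings.

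The rule named Prdm12, the 10 highest and 10 lowest fold changes among genes past the threshold with mean log2 CPM of 0 or more and at least 5 of 6 iKO libraries on the same side of the control median, up to 4 called members of each list by smallest p, and the member with the smallest p where none was called. Unnamed gene models, pseudogenes and sex-chromosome genes were left out of the 20 largest changes. For the sex, agent and interaction comparisons it named the 5 genes with the smallest p in each direction. Genes named outside the rule are said to be so.

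Simulated counts with the real means, library sizes and dispersions were used to test the procedure, with 200 genes changed by 1.5-fold or 2-fold. For iKO against control, 67% of the 1.5-fold and 82% of the 2-fold changes were recovered among 16256 genes, and 5.7% of the calls were false. The shares were 67% and 85% for male against female, 8% and 44% for the interaction, and 20% and 61% for corn oil against tamoxifen. For iKO against tamoxifen-injected controls they were 53% and 83%, and against corn-oil controls 43% and 73%. False calls were 1.94% for the sexes, 8.77% for the interaction and 11% for corn oil against tamoxifen. They were 6.21% for iKO against tamoxifen-injected and 6.45% against corn-oil controls. Each gene was drawn independently, with no shift shared by many genes of a library, so these rates may differ in the real libraries. In the list simulation camera and fry each called the 1 raised list and 0 of 20 untouched lists. Genes varied independently there, so it does not show how often camera at the preset correlation calls lists of correlated genes.

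Alternatives covered DESeq2 size factors and upper-quartile scaling, no filter and a stricter filter (1 CPM in 6 libraries), the DESeq2 1.42.0 Wald test, limma-voom, and models without sex, with the replicate number as a block, with the run of sample numbers as a term, or with 1 surrogate variable from sva 3.50.0. Others restricted the libraries by injected agent, Cre, run or sex, left out each library in turn, or changed the threshold. Chosen after seeing the data were fits without control 6 and iKO 1 together, gene list tests without those libraries, a fit with the myelinating Schwann cell score as a term, and tests of the transcription factor list without Prdm12. All columns of the deposited tables were used. Pairs of libraries within a group differed by far more than sampling noise, with chi-square per degree of freedom from 3.21 to 46.3, so none was treated as a repeat of another. Plots were drawn with matplotlib 3.10.9.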

Results

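Gene expression was measured in dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, of adult mice labelled C57Bl6, in 12 libraries. Prdm12 encodes a PRDM-family zinc finger protein needed for pain-sensing neurons (nociceptors) to form in the embryo, and the series asks which genes depend on it in the adult ganglion. The 6 iKO libraries came from animals with a tamoxifen-activated Cre recombinase at the Rosa26 locus and 2 floxed Prdm12 alleles, studied 1 month after tamoxifen injection. The 6 controls were of mixed kinds. Control 1 carried Cre and 1 floxed allele, controls 2 and 3 carried 1 floxed allele without Cre, and control 4 carried Cre with 0 floxed alleles. All 4 received tamoxifen. Controls 5 and 6 had the genotype of the iKO animals and received corn oil in place of tamoxifen. Controls 1 and 2 and iKO 1 to 3 were female and the other 7 libraries male. P-values measure the spread between these samples, since the labels do not say whether a library is a single animal's ganglia. Tests, gene lists and the rule for naming genes were fixed before the data were examined. Totals ran from 13943784 counts in control 5 to 20377766 in iKO 3, and 24886 to 26592 genes had a count in each library.

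Prdm12 itself was lower in all 6 iKO libraries than in any control. Its level was 117 ± 29.4 CPM in controls and 23.3 ± 2.51 CPM in iKO libraries (SD, n = 6 each), or 19.9% of the control level, and the 2 groups differed by an exact 2-sided permutation test of log2 CPM (p = 0.00216, the smallest that 924 relabellings can give). The log2 fold change was -2.33 ± 0.18 (SE, adjusted p = 8.59e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Control 6 had 64.6 CPM, 50.5% of the mean of the other controls (128 ± 15.6, n = 5), and the iKO mean was 18.2% of that mean. The labels do not say which exons are floxed, so the counts that remain in iKO libraries can come from undeleted exons. Among 18 measured protein-coding genes of the 10 on each side of Prdm12, 0 were called, with a smallest adjusted p of 0.199 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (Fubp3, log2 fold change -0.22). Gm13425, a non-coding gene on the opposite strand that shares 8.09% of Prdm12's exon bases and was singled out after its values were seen, fell from 91.4 ± 6.36 to 56.1 ± 8.91 CPM (SD, n = 6 each, log2 fold change -0.69). Gm13425 was itself called (adjusted p = 0.00157 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Reads from the shared stretch cannot be assigned to either strand in these libraries. Prdm12 lost 94.1 CPM on average and Gm13425 35.3 CPM. Reads spread evenly over Prdm12's exons would place only 8.09% of the former in the shared stretch, which argues against shared reads as the whole cause. How reads were spread over the exons was not examined.

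**Figure D1:**
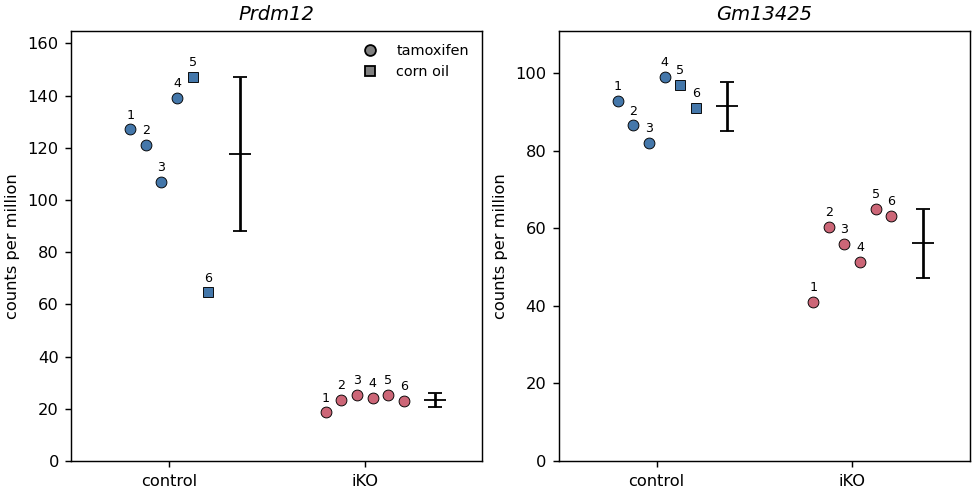
Expression in CPM (y axis) of Prdm12 and of Gm13425, the gene on its opposite strand, in each control and iKO library; digits are replicate numbers, circles tamoxifen, squares corn oil, and bars mean ± SD of 6 libraries. All iKO libraries lie below all controls for both genes, while control 6 is low for Prdm12 (64.6) but not for Gm13425 (91.1).

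Loss of Prdm12 went with a moderate change in the rest of the transcriptome. In iKO ganglia 155 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 88 higher and 67 lower, out of 16384 (1559 at an unadjusted p under 0.05). DESeq2 called 294 and limma-voom 157. Drd1, the dopamine D1 receptor, rose most among the named genes, from 0.429 ± 0.0892 to 1.92 ± 0.46 CPM (SD, n = 6 each, log2 fold change 2.08 ± 0.21 SE). Stk32a, a serine/threonine kinase gene, rose from 20.9 ± 2.94 to 52.3 ± 4.93 CPM (1.32 ± 0.10 SE) and had the smallest adjusted p of all genes, 1.29e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Creg2 fell from 27.4 ± 3.85 to 9.73 ± 2.52 CPM (-1.46 ± 0.15 SE), and Grik1, a kainate-type glutamate receptor subunit and the most abundant of the named genes that fell, went from 488 ± 68.6 to 264 ± 24.9 CPM (-0.87 ± 0.09 SE).

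The other large increases were in genes of several kinds. Chrna6, the α6 nicotinic acetylcholine receptor subunit, rose from 109 ± 10.7 to 231 ± 28.2 CPM (SD, n = 6 each, 1.09 ± 0.09 SE on the log2 scale). Transcriptional regulators among them were Nkx6-2, a homeobox factor (1.56 ± 0.30 SE), and Skor2, a SKI-family corepressor (1.20 ± 0.13 SE). Cyp26b1, which breaks down retinoic acid (1.13 ± 0.13 SE), Grem1, a secreted BMP antagonist (2.83-fold), and Rgs9bp, an anchor of the GTPase activator RGS9 (1.54 ± 0.16 SE), also rose, as did Wscd1 (1.32 ± 0.20 SE) and Atp6ap1l (1.07 ± 0.10 SE). Of these, Drd1, Nkx6-2, Grem1, Rgs9bp and Wscd1 averaged under 2 CPM in controls. Nkx6-2 shares 12.9% of its exon bases with Inpp5a on the other strand, at 21.2 CPM, so its low counts can hold reads of that gene.

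Genes that fell included H2-M11, a non-classical MHC class I gene (-2.09 ± 0.39 SE on the log2 scale), Lrrn4 (-1.31 ± 0.17 SE) and Serpina1e of the α1-antitrypsin family (-1.24 ± 0.27 SE). Insrr, a receptor tyrosine kinase related to the insulin receptor, fell by 1.09 (± 0.17 SE), Kcnn3, the SK3 calcium-activated potassium channel, by 1.05 (± 0.17 SE), Dpys, dihydropyrimidinase, by 1.03 (± 0.20 SE) and Fyb2 by 1.03 (± 0.17 SE). Serpina1e, Mrgprb5 and H2-M11 belong to families with closely similar copies, so their counts are uncertain where reads could be shared. Most changes were small, with a median absolute log2 fold change of 0.55 and 27 genes above 1. Over all 16384 genes tested, every iKO library lay above or every one below all controls in 253, where chance gives 0.216% of genes, and 125 of these were among the 155 called.

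**Figure D2:**
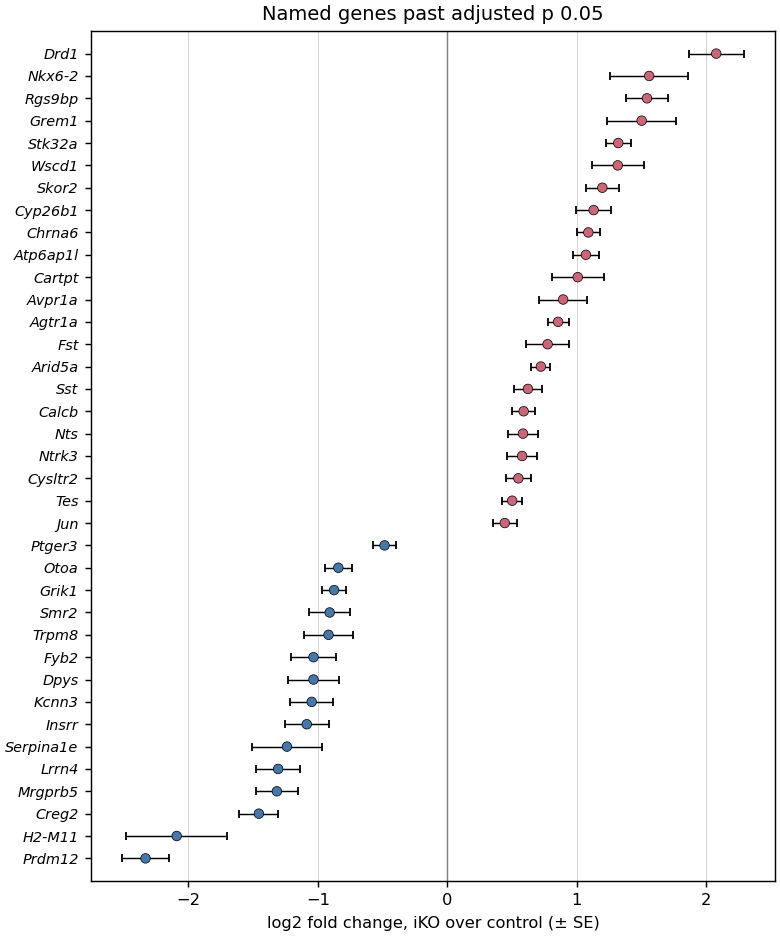
Log2 fold change of iKO over control (x axis) with its standard error for the named genes past adjusted p 0.05, red higher and blue lower in iKO (n = 6 libraries each). Drd1 is the highest at 2.08 and Prdm12 the lowest at -2.33.

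Single nociceptor genes changed in both directions. Of 15 peptidergic nociceptor genes, 3 rose and 1 fell (3 and 4 adjusted over the list alone). Calcb, which encodes β-CGRP, rose from 141 ± 20.4 to 212 ± 10.5 CPM (SD, n = 6 each, 0.59 ± 0.09 SE on the log2 scale), Cartpt, the CART peptide gene, rose by 1.01 ± 0.20, and Avpr1a, a vasopressin receptor, by 0.90 ± 0.18, while Smr2 fell by 0.91 ± 0.16. The α-CGRP gene Calca was at 1320 ± 101 and 1290 ± 40.6 CPM (log2 fold change -0.03 ± 0.07 SE). The list had a median of -0.06 and a mean of 0.02, and camera's direction was down (adjusted p = 0.694). Of 18 nonpeptidergic nociceptor genes, 1 rose and 3 fell (2 and 6 adjusted over the list alone). Agtr1a, an angiotensin receptor, rose by 0.86 ± 0.08, while Mrgprb5, a Mas-related receptor (-1.32 ± 0.16), Grik1 (-0.87 ± 0.09) and Otoa (-0.84 ± 0.10) fell. This list was called lower by camera (adjusted p = 0.0205, median -0.10, adjusted p = 0.879 with an estimated correlation). That call was lost without control 1 (adjusted p = 0.096), control 4 (0.0553), iKO 1 (0.149, median -0.06) or iKO 4 (0.106), and the median was -0.18 without the corn-oil controls.

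Among itch-related (NP3) genes 3 of 10 rose and 0 fell, and the counts were the same adjusted over the list alone. These were Sst, the somatostatin gene (0.62 ± 0.11 SE on the log2 scale), Nts, neurotensin (0.58 ± 0.12), and Cysltr2, a leukotriene receptor (0.55 ± 0.10). The list's median was -0.02, its mean 0.13 and camera's direction up (adjusted p = 0.136). Markers of cold-sensing neurons were all lower. Trpm8, the cold and menthol receptor, fell from 52.5 ± 10.4 to 27.5 ± 7.32 CPM (SD, n = 6 each, -0.92 ± 0.19 SE), and the other 5 of the 6 genes had negative fold changes without being called (2 of 6 lower adjusted over the list alone). The list was called lower by camera, with a median of -0.33 (adjusted p = 0.00445, adjusted p = 0.879 with an estimated correlation). Of 10 genes of C-fibre low-threshold mechanoreceptors 0 were called (1 higher adjusted over the list alone, Piezo2 at 0.30 ± 0.08 SE, median 0.01). Of 18 genes of large-diameter neurons 1 rose, in both counts: Ntrk3, the neurotrophin-3 receptor, went from 467 ± 48.7 to 689 ± 118 CPM (SD, n = 6 each, 0.58 ± 0.11 SE), with iKO 1 at 461 CPM (list median 0.05).

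Neuropeptide genes had 4 called members of 15 measured, all higher (4 higher and 1 lower adjusted over the list alone): Calcb, Cartpt, Sst and Nts. The list as a whole was not called by camera (median 0.01, adjusted p = 0.0594, and 0.879 with an estimated correlation). With the replicate number as a block and the preset correlation camera called it (adjusted p = 0.00632). Of 19 axon injury genes 4 rose (4 higher and 2 lower adjusted over the list alone). These were Arid5a (0.72 ± 0.07 SE on the log2 scale), Fst, the follistatin gene (0.77 ± 0.16), Tes (0.50 ± 0.08) and Jun (0.44 ± 0.09). Camera did not call this list (median 0.07, adjusted p = 0.0949, and 0.879 with an estimated correlation), but did with the block (adjusted p = 0.0423). The mixed fry test, which asks for change in either direction, gave adjusted p = 6.81e-07 for the neuropeptides and 4.31e-10 for the injury genes. It gave 6.81e-07 for the peptidergic, 1.59e-08 for the nonpeptidergic and 3.8e-06 for the NP3 list. Apart from the transcription factor list below, no list was retested without its called members, so these values can rest on few genes. The neuropeptide list shares Calcb and Cartpt with the peptidergic list, and Sst and Nts with the NP3 list. Of the injury genes, named outside the rule, Atf3 (0.235 ± 0.145), Gal (-0.266 ± 0.153), Gap43 (-0.071 ± 0.06) and Sox11 (0.098 ± 0.125) were not called.

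Of 34 transduction and ligand-gated channels 1 rose (Chrna6) and 2 fell, Grik1 and Trpm8 (2 and 5 adjusted over the list alone, median -0.03, mixed fry adjusted p = 1.68e-08). Of 43 receptors with roles in nociception 0 rose and 2 fell, Mrgprb5 and the prostaglandin receptor Ptger3 (-0.48 ± 0.09 SE on the log2 scale), with 1 and 3 adjusted over the list alone (median -0.01, mixed fry adjusted p = 0.00522). The list of 36 voltage-gated channels also holds some potassium channels of other kinds. In it 0 genes were called in either count by edgeR's quasi-likelihood test. Kcnv1 had the smallest p (0.41 ± 0.11 SE, list median 0.04). Of 41 sensory neuron transcription factors Prdm12 alone was called over all genes (2 higher and 2 lower adjusted over the list alone, median 0.04, mean -0.03). Without Prdm12 itself, 0 of the other 40 were called (2 higher and 1 lower adjusted over the list alone, mean 0.03, mixed fry adjusted p = 0.241). Of 14 genes of the general sensory neuron list 0 were called in either count (median 0.04), with Uchl1 at 0.13 ± 0.07 SE. Of 9 measured genes of visceral and autonomic neurons 0 were called (1 higher adjusted over the list alone, Slc5a7 at 0.69 ± 0.20 SE, list median -0.02 and mean 0.02). Of 13 genes of neurotrophic signalling Ntrk3 was called (2 higher and 1 lower adjusted over the list alone, median 0.11, mixed fry adjusted p = 4.07e-06). Among 18 PRDM family members and chromatin partners of PRDM12, 0 were called (1 higher adjusted over the list alone, Prdm8 at 0.37 ± 0.09 SE, median -0.01).

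**Figure D3:**
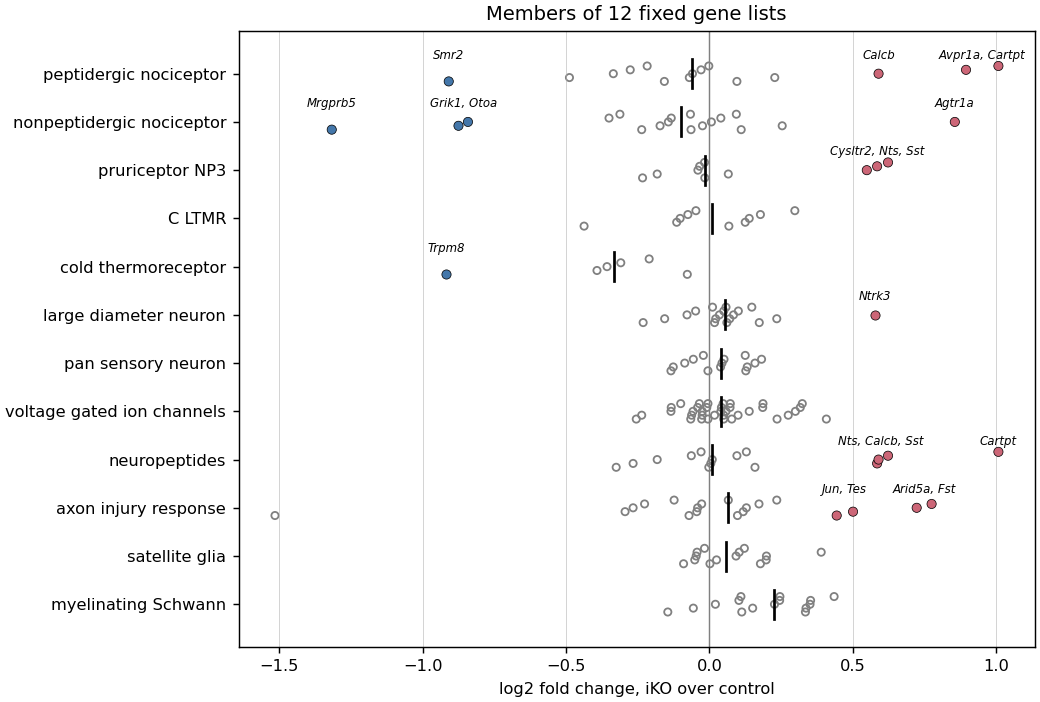
Log2 fold change of iKO over control (x axis) of each measured member of 12 fixed gene lists (y axis); filled points are past adjusted p 0.05 over all genes and named, open points are not, and vertical bars are list medians. The called nociceptor genes lie on both sides of 0, and the 6 cold thermoreceptor genes all lie below it.

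Markers of other cells in the ganglion showed 0 called genes. Of 15 myelinating Schwann cell genes 13 had positive fold changes and 0 were called (1 higher adjusted over the list alone). Camera called the list higher, with a median of 0.23 (adjusted p = 0.00283, adjusted p = 0.879 with an estimated correlation). The median was 0.13 without iKO 1, which had the highest score for this list (0.45), and 0.15 without control 3. Camera also called erythroid genes (7 measured, median -0.80, adjusted p = 0.00159) and cell cycle genes (14 measured, median -0.47, adjusted p = 0.00159) lower, both with adjusted p = 0.879 with an estimated correlation. For these lists 0 members were called in either count, Hbb-bt of the β-globins being at -0.90 ± 0.42 SE and Ccna2, cyclin A2, at -0.53 ± 0.18 SE. Both calls were lost without the corn-oil controls (medians -0.44 and -0.30, adjusted p = 0.162 and 0.173 by camera). By fry, which tests a list on its own, 0 of the 38 lists were called in a single direction.

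No called member in either count was found by edgeR's quasi-likelihood test among 14 satellite glia genes (median 0.06, Fbln5 0.18 ± 0.09 SE on the log2 scale), 18 macrophage genes (-0.05, Trem2 0.30 ± 0.26), 7 MHC class II genes (-0.02, Ciita -0.36 ± 0.21), 10 lymphocyte genes (-0.21, Cd79b -0.56 ± 0.34), 10 neutrophil genes (-0.35, Elane -0.62 ± 0.50) or 12 endothelial genes (-0.08, Tek -0.20 ± 0.17). The same held for 11 skeletal muscle genes (-0.60, Myh4 -1.05 ± 0.74), 8 adipocyte genes (-0.07, Plin4 0.35 ± 0.31) and 5 spinal cord genes (0.15, Gad1 0.40 ± 0.28). Mural cell genes (9 measured, median 0.12, camera's direction down) and fibroblast genes (12 measured, -0.02) each had 0 called and 1 lower adjusted over the list alone, Rgs5 (-0.25 ± 0.07) and Postn (-0.34 ± 0.10). By exact permutation tests of marker scores the smallest unadjusted p were 0.0303 for cold thermoreceptors and 0.0455 for nonpeptidergic nociceptors (smallest adjusted p 0.773). With 38 lists and a smallest possible p of 0.00216, a single fully separated list could not have passed 0.05 after adjustment. The iKO 1 library stood apart from the other 5 iKO libraries, with scores of 1.13 for macrophages, 1.10 for fibroblasts, 0.85 for endothelium and -0.29 for sensory neurons.

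Lists for stress and metabolism also held few called genes. The immediate early list had Jun alone of 16 higher, in both counts (median -0.08), and the estrogen response list Cyp26b1 alone of 11, in both counts (median -0.09, mean 0.03, camera's direction up, mixed fry adjusted p = 0.00507). Glucocorticoid and acute phase genes had 0 of 14 called and 1 adjusted over the list alone, Fkbp5 (0.61 ± 0.13 SE on the log2 scale, median 0.16). In neither count was a member called among 14 p53 targets (median 0.04, Sesn2 0.42 ± 0.14), 18 interferon response genes (-0.08, Gbp2 -0.86 ± 0.47), 24 cholesterol synthesis genes (-0.03, Srebf2 0.20 ± 0.07) or 21 oxidative phosphorylation genes (0.05, Uqcrq 0.18 ± 0.08). Sex-chromosome genes had 0 of 9 called between iKO and control in either count, with Eif2s3y at -0.19 ± 0.11 SE.

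**Figure D4:**
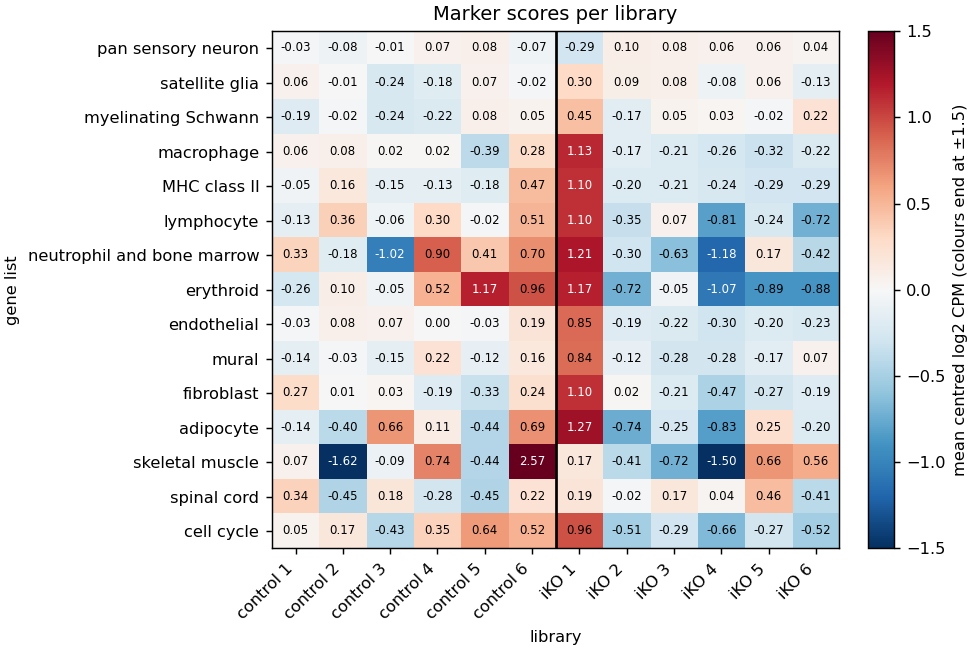
Marker scores, the mean centred log2 CPM of each gene list (y axis), in each library (x axis), with the score printed in each cell and colour from blue (low) to red (high). The iKO 1 library has the highest macrophage (1.13), MHC class II (1.10) and endothelial (0.85) scores, and control 6 the highest skeletal muscle score (2.57).

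The number of called genes depended on single libraries and on the controls used. It was 364 without iKO 1, 92 without control 1, 103 without control 2, 93 without iKO 5 and 97 without iKO 6, and 341 without both iKO 1 and control 6. Sample numbers in the labels form 2 runs, and within replicates 1 to 4 alone 35 genes were called and within replicates 5 and 6 alone (all male) 82, against 162 with the run as a term. Prdm12 had log2 fold changes of -2.41 and -2.13 in these runs, with adjusted p = 5.22e-05 and 0.622 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the named genes, the calls of Trpm8, Avpr1a and Fst were lost on leaving out any of 9 single libraries, Cartpt and Serpina1e any of 8, Jun and Ntrk3 any of 6, Nkx6-2 any of 5, H2-M11, Nts and Dpys any of 4, Ptger3 either of controls 1 and 2, and Smr2 on leaving out control 2. Their highest adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.137 for Trpm8, 0.11 for Avpr1a, 0.141 for Fst, 0.0945 for Cartpt, 0.177 for Serpina1e, 0.0991 for Jun, 0.0739 for Ntrk3, 0.0783 for Nkx6-2, 0.0911 for H2-M11, 0.0911 for Nts, 0.0917 for Dpys, 0.075 for Ptger3 and 0.0566 for Smr2.

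Against the 4 tamoxifen-injected controls, where all libraries had received the same agent, many of the same genes were called. Stk32a (log2 fold change 1.23 ± 0.09 SE), Chrna6 (1.05 ± 0.10), Drd1 (1.98 ± 0.24), Nkx6-2 (2.02 ± 0.29) and Agtr1a (0.80 ± 0.08) rose, and H2-M11 (-2.37 ± 0.32), Otoa (-0.92 ± 0.10), Grik1 (-0.98 ± 0.07), Creg2 (-1.43 ± 0.17) and Prdm12 (-2.40 ± 0.19) fell. Mrgprb5 also fell, with an adjusted p of 2.4e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment that equalled that of Stk32a as the smallest among the named genes. Trpm8 (-0.94 ± 0.22), Cartpt (0.87 ± 0.21), Avpr1a (0.78 ± 0.20), Fst (0.77 ± 0.19), Nts (0.52 ± 0.13) and Ntrk3 (0.59 ± 0.13) were not called against these controls. Against the 2 corn-oil controls, which share the iKO genotype, Stk32a (1.57 ± 0.13), Chrna6 (1.20 ± 0.14), Agtr1a (1.01 ± 0.12), Calcb (0.82 ± 0.11) and Cysltr2 (0.84 ± 0.11) rose and Insrr (-1.48 ± 0.19), Prdm12 (-2.15 ± 0.25), Creg2 (-1.52 ± 0.22) and Grik1 (-0.59 ± 0.10) fell. Mrgprb5 (-0.77 ± 0.15), Otoa (-0.62 ± 0.14), Nkx6-2 (0.79 ± 0.36) and H2-M11 (-1.01 ± 0.46) were not called in that comparison. In all, 222 genes were called against tamoxifen-injected controls (113 higher, 109 lower) and 24 against corn-oil controls (19 higher, 5 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without iKO 1 these became 1459 (978 higher, 481 lower) and 160 (77 higher, 83 lower). Without control 4 the 222 became 305 (204 higher, 101 lower). The 222 became 98 without control 1, 105 without control 3, 143 without iKO 3, 469 without iKO 4, 138 without iKO 5 and 140 without iKO 6. The 24 became 14 without control 3, 3 without control 5 and 5 without control 6, where 1 corn-oil library remains, 15 without iKO 3, 10 without iKO 4, 11 without iKO 5 and 9 without iKO 6.

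Within the controls, corn oil was compared with tamoxifen. Whrn, which encodes the scaffold protein whirlin, was higher with corn oil, at 21.7 CPM against 10.9 CPM in tamoxifen-injected male controls (log2 fold change 1.00 ± 0.13 SE), and Ide, insulin-degrading enzyme, was lower, at 95.3 against 151 CPM (-0.66 ± 0.08 SE). Prx, a myelin protein gene of Schwann cells, had a log2 fold change of 0.56 ± 0.09 SE, Iqsec1 0.57 ± 0.10, Sptbn5 0.64 ± 0.11 and Inpp5j 0.66 ± 0.11, and Btaf1 -0.59 ± 0.09, Rgs17 -0.45 ± 0.08, Rab27b -0.50 ± 0.09 and mt-Rnr2 -0.51 ± 0.10. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called, the smallest adjusted p being 0.0786 for Whrn and Ide, while 2240 genes had an unadjusted p under 0.05 and DESeq2 called 195. Leaving out control 5 gave 18 calls, control 1 7, control 2 6, and controls 4 or 6 3 each. Without control 5 or 6 a single corn-oil library remains, so the tamoxifen-injected controls alone supply the spread. Injected agent, floxed genotype and run of sample numbers are the same split of the controls and cannot be told apart.

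Male and female ganglia differed at sex-linked genes. The Y-linked genes Kdm5d (log2 fold change 8.49 ± 0.18 SE), Eif2s3y (8.59 ± 0.18), Ddx3y (8.57 ± 0.19) and Uty (9.33 ± 0.27) were higher in males, together with Gm29650 (8.07 ± 0.37). Xist, the RNA that silences the inactive X chromosome, was lower in males (-9.31 ± 0.18), at 574 CPM in female and 1.25 CPM in tamoxifen-injected male controls. The X-linked genes Kdm6a (-0.57 ± 0.06) and Kdm5c (-0.47 ± 0.06) and the gene model 5530601H04Rik (-0.51 ± 0.08) were also lower, and Eif2s3x, at -0.57 ± 0.10, was not called. In all, 9 genes were called, 5 higher and 4 lower in males, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Xist and Y-linked counts matched the labelled sex in all 12 libraries.

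Whether the effect of Prdm12 loss differed between the sexes was tested by an interaction term. The smallest p-values belonged to Swt1 (difference of log2 fold changes, male minus female, 0.83 ± 0.19 SE), Serac1 (0.57 ± 0.16), Ints8 (0.37 ± 0.10), Slc5a3 (0.60 ± 0.17) and Zfp933 (0.54 ± 0.15) in the positive direction. In the negative direction they belonged to Gm15609 (-1.53 ± 0.32), Pheta2 (-1.82 ± 0.42), the α-globin genes Hba-a1 (-2.25 ± 0.53) and Hba-a2 (-2.10 ± 0.50), which are near-identical copies, and Plekho2 (-0.76 ± 0.19). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called, with a smallest adjusted p of 0.945, 589 genes at an unadjusted p under 0.05 and 2 genes called by DESeq2. Without iKO 2 there was 1 call, and the named iKO genes had interaction terms such as 0.22 ± 0.36 for Prdm12, 0.10 ± 0.44 for Drd1 and 0.61 ± 0.34 for Trpm8. In simulations this test recovered 8% of 1.5-fold and 44% of 2-fold differences, so most differences of that size between the sexes were not detectable with these libraries.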

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

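The comparison of cell type markers in iKO 1 with the other iKO libraries was chosen after its scores were seen. Each group of 6 libraries was searched for a library far from the rest by a gap test at a level of about 1 in 20, so that 10.4 of 208 groups are expected by chance, and 33 were found. Of these, 27 concern iKO 1.

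In iKO 1 the TMM factor was 1.06 (0.973 to 0.995 in the other iKO libraries). Neuronal scores were low: peptidergic -0.27 (0 to 0.14), nonpeptidergic -0.26 (-0.09 to -0.01) and the general sensory neuron list -0.29 (0.04 to 0.10). Voltage-gated channels were at -0.41 (0.02 to 0.14), transduction channels at -0.34 (-0.04 to 0.07) and nociceptive receptors at -0.28 (-0.03 to 0.07). Scores of other cells were high, with macrophages at 1.13 (-0.32 to -0.17), MHC class II at 1.10 (-0.29 to -0.20), endothelium at 0.85 (-0.30 to -0.19), mural cells at 0.84 (-0.28 to 0.07) and fibroblasts at 1.10 (-0.47 to 0.02). The p53 score was 0.30 (-0.08 to 0.01), interferon 0.59 (-0.27 to 0) and cell cycle 0.96 (-0.66 to -0.27).

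Single genes of iKO 1 followed the same division. Low values, in CPM, were Chrna6 177 (231 to 257 in the other iKO libraries), Prdm12 18.6 (22.9 to 25.4), Ptger3 41.1 (57.5 to 66.8), Ntrk3 461 (673 to 780), Piezo2 765 (994 to 1110) and Uchl1 1400 (1590 to 1670). High values were Uqcrq 139 (97.6 to 109), Hbb-bt 43.4 (9.16 to 21.2), Ciita 6.95 (3.77 to 4.28), Cd79b 4.60 (0.954 to 1.35), Tek 17.4 (8.22 to 10.6) and Trem2 7.16 (1.89 to 3.22).

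A lower share of neurons with the other cells in their usual proportions could give low neuronal markers in iKO 1. The median deviation from the other iKO libraries was 0.21 (-0.084 to 0.47) for satellite glia, which wrap the neuron bodies. It was 1.4 (1.2 to 1.5) for macrophages, so this explanation alone falls short. These intervals come from resampling the genes of each list and do not measure spread between libraries. Fibroblast genes were higher by 1.2, endothelial and mural genes each by 1 and myelinating Schwann cell genes by 0.4, while sensory neuron genes were at -0.36. More connective, vascular and immune tissue around the neurons may account for this, and whether it came from dissection or from the animal was not tested.

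In the other libraries 6 values stood apart. These were the sensory transcription factor score of control 5, 0.15 (-0.04 to 0.02 in the other controls), Lrrn4 in control 4, 4.89 CPM (3.33 to 3.84), Slc5a7 in control 3, 8.68 CPM (3.82 to 5.58), and Myh4, a fast skeletal muscle myosin, in control 6, 47.2 CPM (2.90 to 13.4). The neuropeptide score of iKO 4 was 0.30 (-0.03 to 0.09 in the other iKO libraries) and Gad1 in iKO 5 was 2.33 CPM (1.11 to 1.55). This number lies within what chance gives.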

How the results depend on the processing

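Fits without control 6 and iKO 1 together, the fit with a Schwann cell score and the transcription factor list without Prdm12 were added after seeing the data. Without Prdm12 the mixed fry adjusted p of that list went from 2.3e-07 to 0.241. The cause of the changes below was not tested. Over 1919 values of named genes under an alternative 227 lost a call and 38 gained 1. In 5 the sign changed, for Elane, Gad1 and Hbb-bt in females (0.21, -0.24 and 0.20) and for Trem2 in males and in replicates 5 and 6 (-0.02 in both), and 0 of these were called in either fit.

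The 155 genes called between iKO and control became 253 without a filter, 294 with DESeq2, 341 with 1 surrogate variable, 235 without corn-oil controls (130 shared) and 70 with an absolute log2 fold change of at least 0.58. With fewer libraries the number was 49 with only Cre-carrying controls, 35 in replicates 1 to 4, 82 in replicates 5 and 6, 45 in males and 1 in females. It was 341 without control 6 and iKO 1, and leaving out 1 library gave 92 to 364. The values past 1.5-fold were 92 without control 1, 103 without control 2, 93 without iKO 5, 97 without iKO 6 and 364 without iKO 1. All 155 genes kept their direction in the fits that tested them all. With the replicate number as a block and sex as a term 79 genes were called, 70 of them shared. Pairing by replicate number was not clear: after removing group, the correlation of same-numbered libraries was 0.22, 0.18, -0.15, 0.072, 0.19 and 0.047 for numbers 1 to 6, and the own number was the best match for 1, 2 and 5. After removing sex as well it was -0.22, 0.061, -0.064, -0.096, 0.016 and -0.065.

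Prdm12 ranged from -2.44 to -2.25 when 1 library was left out. Its call was lost in replicates 5 and 6 (-2.13, adjusted p = 0.622 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and in males (-2.24, adjusted p = 0.0616). The 9 genes that differed between the sexes became 16 without a filter and 17 with DESeq2, and 8 to 11 on leaving out 1 library. The 0 genes of the interaction became 270 without a filter, 2 with DESeq2 and 1 without iKO 2, with a range of 0 to 1.

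For corn oil against tamoxifen the 0 genes became 659 without a filter and 195 with DESeq2, with a range of 0 to 18: 7 without control 1, 6 without control 2, 3 without control 4, 18 without control 5 and 3 without control 6. For iKO against tamoxifen-injected controls the 222 became 927 without a filter and 594 with DESeq2. The share of higher genes moved from 50.9% to 72.5% and 63.3%, and was 67% without iKO 1 and 66.9% without control 4. The range was 98 to 1459, with 98 without control 1, 105 without control 3, 1459 without iKO 1, 143 without iKO 3, 469 without iKO 4, 138 without iKO 5 and 140 without iKO 6. For iKO against corn-oil controls the 24 became 349 without a filter and 68 with DESeq2, the share of higher genes moving from 79.2% to 30.9% (108 higher, 241 lower) and 69.1%. Without iKO 1 the share was 48.1% and without control 5 33.3%. The range was 3 to 160, with 14 without control 3, 3 without control 5, 5 without control 6, 160 without iKO 1, 15 without iKO 3, 10 without iKO 4, 11 without iKO 5 and 9 without iKO 6.

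Of the gene lists 5 were called by camera, 0 by fry, 0 with an estimated correlation, 10 with the replicate block and 11 without control 6 and iKO 1. Lists gained with the block were neuropeptides and oxidative phosphorylation (adjusted p = 0.00632 each by camera), neutrophil (0.00676), axon injury and immediate early genes (0.0423 each). Leaving out 1 library gave 4 to 13, with 9 without control 1, 9 without control 2, 8 without control 3, 13 without iKO 1 and 8 without iKO 5. Marker scores passed 0.05 for 0 lists with TMM, DESeq2 size factors and upper-quartile scaling, which says little, since a single fully separated list could not pass after adjustment over 38 lists.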

Other observations

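The genes in the next 2 paragraphs, the comparison limited to tamoxifen-injected libraries, the Schwann cell term and the iKO 1 marker test were chosen after the results were seen.

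Among called genes outside the fixed lists were single potassium channel genes, with no test of such genes as a group. Kcnj11, the Kir6.2 subunit of the ATP-sensitive channel, fell by 0.75 on the log2 scale in iKO ganglia, Kcnk9, the K2P channel TASK-3, by 0.67 and Kcnmb1, a β subunit of the large-conductance calcium-activated channel, by 0.69, while Kcnab1 rose by 0.30. The fixed list of 36 voltage-gated and related channels held 0 called genes. It includes relatives such as Kcnn1 and Kcnk2 but not Kcnn3 or the genes above, so no contrast between channel classes follows.

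Among the receptor genes that rose were Gpr151, an orphan receptor (0.95), Htr5b (0.74) and the netrin receptor gene Unc5b (0.57). The transcriptional cofactor gene Lmo1 rose by 0.81 and Ngb, neuroglobin, by 0.57.

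The called genes could reflect tamoxifen, control genotype or tissue content rather than loss of Prdm12. Among the 10 tamoxifen-injected libraries 83.9% of the 155 genes (130) were called again, and all 155 kept their direction. These 10 are among the 12 libraries that chose the 155, so agreement in direction was largely built in. The 130 differed where every library had tamoxifen, so the injection alone does not account for their calls. Genes called in replicates 1 to 4 moved in replicates 5 and 6, where all genotypes are alike, by 0.71 of their first change (0.64 to 0.92). For these 33 genes most of the change thus remained where no control lacked floxed alleles or the Cre gene. The groups of replicates 5 and 6 differ in injected agent, however, so genotype was not isolated there. Tamoxifen-activated Cre was present in all iKO libraries but, among controls, only in 1 and 4. An effect of active Cre could move genes in both sets of replicates, so comparing the sets cannot exclude it. Tamoxifen alone could not separate the groups in replicates 1 to 4, where every library had it. With only Cre-carrying controls, and so fewer libraries, 49 genes were called, 46 of them among the 155. All 155 kept their direction in that fit, but 20 of 37 named genes lost their call. Bracketed intervals here come from resampling genes and do not measure spread between libraries. With the Schwann cell score as a term 73.5% stayed called (114 genes) and all 155 kept their direction, with a median absolute log2 fold change 0.95 of the former and a median of the gene-by-gene ratios of 0.978, so Schwann cell content does not account for most of them, though 9 of 37 named genes lost their call. For the 82 genes called from replicates 5 and 6, 19 of which were also called from replicates 1 to 4, the move in replicates 1 to 4 was 0.58 (0.24 to 0.77), and for the 100 genes with the smallest p there 0.63 (0.4 to 0.79, 89% with the same sign). A part of the change may be due to tamoxifen, but this test cannot tell. Genes chosen for a small p in 1 set tend to move less in another, which also holds for the 0.71 above.

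Prdm12 in control 6 was 64.6 CPM, and a sample swap or partial recombination could explain it. The highest iKO library had 25.4 CPM, so an exchanged iKO sample is ruled out. If iKO RNA had been mixed in, other called genes would lie as far towards iKO as Prdm12 (0.61 of the way), but their median position was 0.19 (0.13 to 0.29), and Gm13425 was at 91.1 CPM against a control mean of 91.4. Partial loss of Prdm12 in this animal cannot be told from features shared with control 5, the other corn-oil library, whose median position was 0.29 (0.21 to 0.38) with high Prdm12. A count of reads over the floxed exons, not analysed here, would separate these. The bracketed intervals of the median positions come from resampling genes, not libraries.

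Whether an arbitrary division of the libraries gives as many genes was tested by splits that ignore the labels. Apart from the real one they were drawn at random, so other splits were not tested. There were 462 possible splits for iKO against control, 792 for the sexes and 210 for the tamoxifen-injected libraries. Of 100 splits only 1, the real one, gave as many genes, for iKO against control (155, highest other 125), for the sexes (9, highest other 4) and for iKO against the tamoxifen-injected controls in their own fit (235, highest other 153). The split with 125 genes joined iKO 2, 3, 4 and 6 with controls 1 and 2, so it kept part of the real grouping. The test of tissue content in iKO 1 gave 0.21 for satellite glia.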
